A study of Homo sapiens with 4 samples.

How the data were processed

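RNA was sequenced from LP-1 multiple myeloma cells in 2 control libraries and 2 libraries with SRSF1 knockdown. Per the labels' protocols, total RNA was extracted with a mirVana kit, its integrity was checked, and libraries were made with a TruSeq stranded mRNA kit, which selects polyadenylated RNA, and sequenced as paired ends on an Illumina HiSeq instrument. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq, DESeq, Bowtie2 and StringTie. Their versions, the genome build, the annotation and whether reads were counted by strand are not given in the sources used here. No deposited read alignments were used.

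The values were used as the authors deposited them. The gene table holds a whole-number count of reads per gene and library, not normalised, per the file headers and values. A second deposited table gives FPKM per gene, that is fragments scaled to gene length and library size by the authors. The authors' comparison tables give a log2 fold change of knockdown over control per gene and per transcript, from their normalised means, per the file headers. They also give a p-value and an adjusted p-value from the authors' test, per the file headers. The transcript table holds a signal per transcript and library, deposited by the authors without naming its unit. The 5 splicing tables, with the column names and file type of rMATS junction-count output, hold for each event the junction reads that include or skip it, the inclusion level after the authors' division by effective length, and the authors' p-value and FDR, per the file headers. The authors' KEGG table gives an enrichment ratio per term (the share of their gene list in the term over the share of the background) with its p-value. The deposited GO table was not used here, because its p-values are 0 for terms of 1 or 2 genes. A deposited table of read statistics gives the reads before and after filtering.

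Before filtering there were 106.06 and 116.11 M reads in the control libraries and 117.0 and 104.95 M in the knockdown libraries, and 104.42, 114.34, 115.25 and 103.24 M afterwards, per the authors' deposited table of read statistics. Of bases, 96.58%, 96.59%, 96.58% and 96.47% reached Q30 in that deposited table. Gene count totals were 41280215, 44939687, 43933272 and 39240507, and the 10 most abundant genes took 5.38%, 5.40%, 5.92% and 6.01% of them. At this depth a gene at 1 CPM has about 40 reads per library, and the tested cassette events had a median of 187 junction reads per library. The count table lists 20030 genes, of which 4598 had no read, and no value was assigned to anything but a gene. A spreadsheet had turned 27 symbols into dates, which were repaired from their Entrez identifiers.

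Each library was mapped to its group by its title. The splicing tables name their sets only as first and second, so the sets were identified from the data: over 8388 genes the difference in junction reads between the sets was compared with the labelled gene counts. The first set correlated with the knockdown libraries at 0.886 to 0.922 and with the control libraries at -0.9 to -0.91, and the second set with the control libraries at 0.875 to 0.923. The first set was therefore taken as knockdown. The columns of the splicing tables carry no replicate numbers, so "first" and "second" of a splicing result mean the order in the cell. Each position correlated best with the library of the same number (0.917 to 0.923, against 0.875 to 0.892 with the other of its group), so the position served as the number in the splicing block. For mutually exclusive exons the exon of the inclusion form was read from the effective lengths, as the exon of lower coordinates on the plus strand (100% of 946 events) and of higher coordinates on the minus strand (0.0% of 877 events had it as the lower).

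Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit) on the counts as deposited, with TMM scaling and filterByExpr at a minimum count of 10, which kept 12586 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 and was also counted at an absolute log2 fold change of at least 1. The common dispersion was 0.000625. CPM are scaled by the TMM factors, which lay between 0.9739 and 1.025. For a gene with fewer than 3 control reads the depth-scaled ratio is given with an exact interval instead of a fitted fold. Gene lists, 39 in all and written before the data were examined, were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, which held for 33 lists. Camera with an estimated correlation and fry were run beside it, and the list p-values were adjusted by Benjamini-Hochberg over the lists. Members were counted from the gene test, adjusted over all genes and again over the list alone.

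Splicing events with at least 20 junction reads in every library were tested with edgeR's quasi-likelihood test on inclusion and skipping reads together, with a coefficient per library and the interaction of read kind and group as the tested term. P-values were adjusted by Benjamini-Hochberg within each event type, and an event was called changed at an adjusted p under 0.05 and a difference of mean inclusion of at least 10 points. The dispersion of this test was set to 0 so that the quasi-likelihood part carries the spread between libraries. That spread is moderated across events, so an event's own spread enters the p-value only in part. RASA4, with knockdown libraries at 80.9% and 13.5%, had an adjusted p of 9.59e-15 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The dispersion of 0 was chosen on simulated libraries after the data were available. There, with shifts put only on events of intermediate inclusion, the estimated negative binomial dispersion first written recovered fewer shifts of 20 points. It found 14% of cassette exons and 43% to 74% of the other types, against 41% and 65% to 84%. The first setting was kept as an alternative. The simulation gave all events the same small spread between libraries, so it cannot show how either setting behaves where replicates differ widely. Direction was tested with two-sided exact binomial tests over events, adjusted over event types. Motifs were counted in exon sequences taken from GENCODE 29 transcripts, since no genome was at hand, and densities were compared by permutation over exons with 100000 resamples (unchanged exons had an adjusted p of at least 0.5 and inclusion of 10 to 90%). Overlap of calls was tested with Fisher's exact test and, over 4 bins of expression, an exact Mantel-Haenszel test. Transcripts were tested with limma (trend, robust) on log2(signal + 1) of transcripts at 1 or more in at least 2 libraries. A fold change on that scale understates the change of low transcripts.

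The tests, the thresholds, the gene lists and most alternatives were chosen before the data were examined, apart from the dispersion of the splicing test. So was the rule for named genes: SRSF1, then the 10 genes with the largest rise and the 10 with the largest fall among changed genes at 5 CPM or more in the higher group, with groups that do not overlap and an ordinary symbol, then up to 4 members of each list with the smallest adjusted p, any SR family or reported SRSF1 target gene, and the splicing events with the largest changes (5 cassette exons each way, 2 each way for other types) or in genes of 6 of the lists. Some genes and events that this rule selects are not reported here, and counts include them. Alternatives were the size factors of DESeq2, scaling by library size only, no filter or at least 10 reads in every library, DESeq2 (1.42.0), limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the authors' deposited calls, the replicate number as a block, and leaving out each library. For splicing they were at least 10 or 50 junction reads, differences of 0.05 or 0.2, an adjusted p under 0.01 and the authors' deposited FDR, and for transcripts scaling to equal library totals and no filter. A minimum of 20 reads of the rarer form and the authors' transcript calls were added after the data were seen. The negative binomial dispersion was the setting first written and became an alternative then.

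Each test was also run on simulated data built from the real values. For genes (12464 in the step), edgeR's quasi-likelihood test recovered 86.4% of genes changed 1.5-fold, 97% at 2-fold and 100% at 4-fold, and called 11 of 12267 unchanged genes. For splicing, shifts were put only on events of intermediate pooled inclusion, 100 per size and type (51 for retained introns). Recovery meant an adjusted p under 0.05, whatever the fitted size. A shift of 20 points was recovered in 41% of these cassette exons (47457 events in the step), 65% of 3' splice sites (4718) and 68% of 5' splice sites (3518). It was recovered in 84% of mutually exclusive exons (7084) and 72.5% of retained introns (1183). A shift of 10 points was recovered in 2% of these cassette exons. For transcripts (23116 in the step), shifts were put only on those above a minimum mean signal, 100 of each size. Limma recovered 33% of them at a log2 change of 1 and 75% at 2, and called 9 of 22916 unchanged transcripts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for tables and figures.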

Results

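Gene expression and splicing were measured by stranded, poly(A)-selected RNA sequencing in LP-1, a human multiple myeloma cell line, with and without knockdown of SRSF1, a splicing factor of the serine/arginine-rich (SR) family that binds purine-rich exonic sequence. The series asks how loss of SRSF1 alters expression and splicing in myeloma cells. There were 2 control and 2 SRSF1 knockdown libraries. The gene count totals were 41280215 and 44939687 reads in the control libraries and 43933272 and 39240507 in the knockdown libraries, and 13855, 13887, 14654 and 14530 genes had at least 1 read. Counts differed between replicates by more than sampling noise alone (chi-square per degree of freedom 3.98 in control and 2.59 in knockdown), so each library was treated as a separate sample. Between groups the same measure lay between 291 and 321. No label says that the replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

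SRSF1 (Entrez gene 6426), the targeted gene, was lower in both knockdown libraries. Its level was 673 and 671 CPM (counts scaled to library size) in the control libraries, from 27065 and 29547 reads, and 286 and 287 CPM in the knockdown libraries, from 12876 and 11512 reads. The mean fell from 672 ± 1.49 CPM to 286 ± 0.752 CPM (SD, n = 2 per group), a ratio of 0.426. The log2 fold change was -1.23 (SE 0.0295), with an adjusted p of 3.34e-24 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At the transcript level NM_006924.4, the more abundant of the 2 SRSF1 transcripts tested, fell from 140.2 ± 1.94 to 57.6 ± 0.949 in the deposited signal, a log2 change of -1.27 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00231). The other, NM_001078166.1, measured 14.2 ± 0.735 in control and 12.6 ± 0.425 in knockdown (limma with Benjamini-Hochberg adjustment, adjusted p = 0.311).

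The libraries separated by group at most expressed genes. Of 12586 genes tested with edgeR's quasi-likelihood test, 10081 changed at an adjusted p under 0.05, 5050 of them higher and 5031 lower in knockdown. With so many genes called, this even split depends on the scaling, and direction is relative to it. Under TMM the median log2 change of all genes was 0.0083. By library size only, 5603 genes were higher and 4474 lower. In 11267 genes (89.5%) both libraries of 1 group lay above both of the other, where chance gives 33.3%. The replicates lay close together (biological coefficient of variation 0.025), so that small differences passed the test. At least 2-fold changes were fewer and mostly upward, with 1743 genes higher and 583 lower. The 2-fold split differed on the FPKM scale, which was fitted to the 9897 genes at an FPKM of at least 1 in 2 libraries. On log2(FPKM + 1), where a gene of low expression cannot reach a large change, limma called 324 genes at least 2-fold higher and 364 lower. Without that filter it called 324 and 363. On log2(FPKM + 0.1) limma called 576 higher and 502 lower. That fit was run only with the filter, so filter and constant cannot be told apart there.

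The largest rises were in genes of low expression in control cells, TXNIP excepted. UPB1, an enzyme of pyrimidine breakdown, had 1 read over both control libraries and 797 over both knockdown libraries, a depth-scaled ratio of 826 with an exact 95% interval of 148 to 3.27e+04 that covers counting error only. MT2A, a metal-binding metallothionein, rose from 0.0838 ± 0.0222 to 11.7 ± 0.139 CPM, a log2 change of 7.09 (SE 0.233). FOS, a subunit of the AP-1 transcription factor, rose from 1.10 ± 0.215 to 52.8 ± 2.80 CPM (log2 change 5.57, SE 0.0984). DUSP5, a phosphatase that acts on the kinase ERK, rose from 0.792 to 29.9 CPM (log2 change 5.23, SE 0.115), and ATF3, a stress-induced transcription factor, from 1.33 to 26.7 CPM (log2 change 4.33, SE 0.111). TXNIP, an inhibitor of thioredoxin and of glucose uptake, was the most abundant of these genes in knockdown and rose from 13.6 ± 1.34 to 279 ± 1.77 CPM, a log2 change of 4.37 (SE 0.045). FSD2, BEST1, NSG2 and C3AR1, the receptor of complement fragment C3a, rose by log2 changes of 5.42, 5.13, 4.56 and 4.44. Among these 10 genes the highest adjusted p was 5.33e-16 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and both knockdown libraries lay above both control libraries in each. MT2A shares sequence with other metallothionein genes, so its counts carry that uncertainty.

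The largest falls included an adhesion molecule and several genes of cell division. PECAM1, an adhesion receptor of endothelial and blood cells, fell from 179 ± 1.88 to 18.6 ± 1.87 CPM, a log2 change of -3.27 (SE 0.0473). CDC25B, a phosphatase that activates mitotic cyclin-dependent kinase, fell from 273 ± 2.71 to 40.2 ± 1.26 CPM (log2 change -2.77, SE 0.0353), and CENPE, a kinetochore motor, from 89.9 ± 9.76 to 15.5 ± 0.496 CPM (log2 change -2.54, SE 0.0715). CDC20, which directs the anaphase-promoting complex, fell by a log2 change of -2.35 (198 to 38.6 CPM), and E2F2, a transcription factor of S-phase entry, by -2.23 (342 to 73.1 CPM). DNMT3B, a DNA methyltransferase, fell by -2.25, MET, the receptor of hepatocyte growth factor, by -2.43, and PRTN3, a neutrophil protease, by -2.81. The histone genes HIST1H2BJ and HIST1H2BC fell by -3.22 and -2.51, with the limit that copies of near-identical sequence can share their reads. The highest adjusted p among these 10 genes was 3.53e-13 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), with both knockdown libraries below both control libraries in each.

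**Figure D1:**
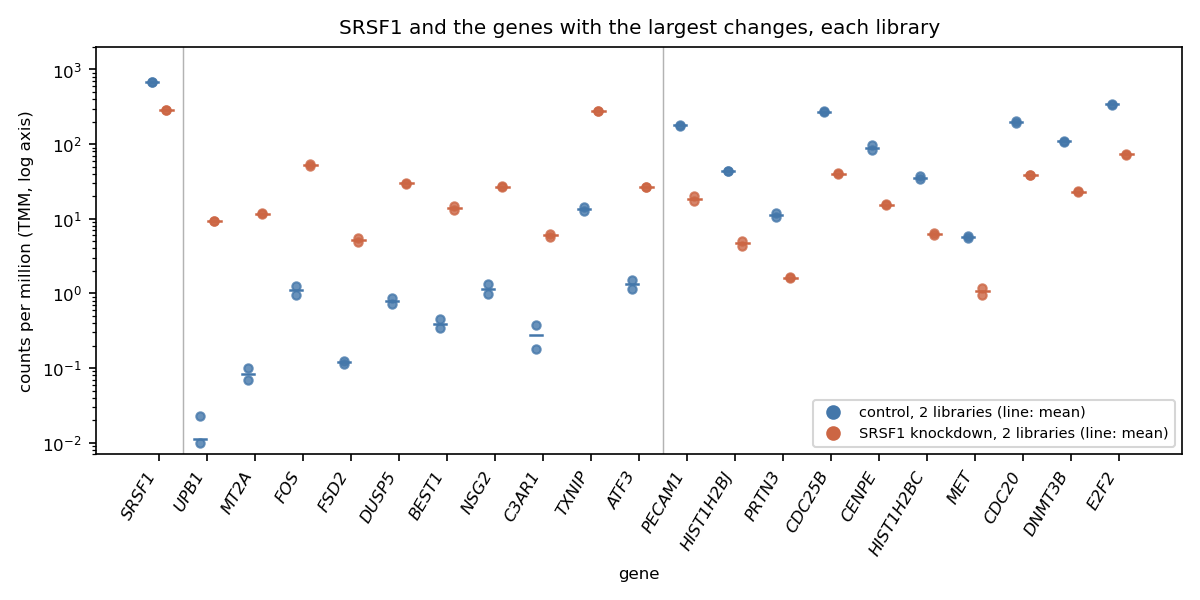
Normalised CPM on a log axis for SRSF1, the 10 genes with the largest rises and the 10 with the largest falls, with 1 point per library, a line at the mean of the 2 libraries, and a control library without reads drawn at the foot of the axis (UPB1). SRSF1 lies at 673 and 671 CPM in control and at 286 and 287 CPM in knockdown.

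Gene groups were compared next, to see which cell functions moved together. Every S-phase and every G2/M-phase gene tested fell. All 47 S-phase genes were lower, with a median log2 change of -1.41, among them RRM2, a subunit of ribonucleotide reductase (-1.95, SE 0.0314, 496 to 129 CPM), the sliding clamp PCNA (-1.65) and the replicative helicase subunits MCM5 (-1.64) and MCM4 (-1.53). The S-phase list had a camera adjusted p of 1.43e-15, and adjusted p = 0.198 with an estimated correlation. All 54 G2/M-phase genes were lower, with a median of -1.60, including the mitotic kinases PLK1 (-2.21, SE 0.0339, 265 to 57.2 CPM) and AURKA (-2.07) and the proliferation marker MKI67 (-2.08, 619 to 146 CPM). Camera gave an adjusted p of 2.46e-17, and adjusted p = 0.198 with an estimated correlation. A list of 25 cell cycle regulators held cyclins, cyclin-dependent kinases, their inhibitors, the phosphatase CDC25A, and genes of the E2F and RB families. Of these, 21 fell and 4 rose (median -0.50), with CCNB1 at -2.05, CCNA2 at -1.87 and CDC25A at -1.90. For this list camera gave an adjusted p of 0.000193, and adjusted p = 0.411 with an estimated correlation. The 4 that rose were all inhibitors (CDKN1C, CDKN1A, CDKN2D and CDKN2B), while the inhibitors CDKN1B, CDKN2A and CDKN2C fell. Of 37 DNA repair genes of the ATM, ATR and Fanconi pathways, 34 fell, 2 rose and 1 did not pass (median -0.86), with FANCI at -1.50, H2AFX at -1.80, CHEK1 at -1.66 and PARP1 at -1.02 (camera adjusted p = 1.64e-08, and adjusted p = 0.198 with an estimated correlation). Among 12 replication-dependent histone genes 9 fell and 2 rose, with HIST1H1C at -1.77 and HIST1H2AC at 0.54, and the list did not pass (median -0.58, camera adjusted p = 0.0552). Poly(A) selection captures these histone messages poorly, since most lack a poly(A) tail. For every list, the counts of higher and lower genes adjusted over the list alone equalled those over all genes tested. Camera with an estimated correlation passed none of the 33 lists, the lowest adjusted p being 0.198. That loss did not come from a larger correlation in every list. The estimate was 0.01 for S-phase genes, equal to the preset. It was lower for DNA repair (0), immediate early (-0.006) and SR family genes (-0.042). Other lists had higher estimates, up to 0.79 in ribosomal protein genes.

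Genes of the splicing machinery fell as groups. Of 21 SR family genes, which include the targeted SRSF1, 18 were lower and 3 higher (median -0.39, camera adjusted p = 0.00121, and adjusted p = 0.246 with an estimated correlation). SRSF2 fell from 982 ± 4.23 to 379.8 ± 4.85 CPM (log2 change -1.37, SE 0.0303) and SRSF3 from 453 ± 13.2 to 219 ± 0.217 CPM (-1.05, SE 0.0302), while RSRP1 (0.51) and SRRM2 (0.25) rose. SRSF5 (0.09) and SRSF6 (-0.09) moved least: by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their adjusted p rose to 0.111 without the first knockdown library for SRSF5 and to 0.076 without the second for SRSF6. Of 25 hnRNP genes, whose proteins bind pre-mRNA and often oppose SR proteins, 22 fell and 1 rose (median -0.52, camera adjusted p = 2.24e-06, and adjusted p = 0.246 with an estimated correlation), with HNRNPAB at -1.11 and PTBP1 at -0.95. Of 41 core spliceosome genes 38 fell and 2 rose (median -0.50, camera adjusted p = 6.5e-08, and adjusted p = 0.25 with an estimated correlation), including U2AF2 (-0.93), SNRPD1 (-1.01) and SNRPG (-1.10). The 8 kinases of SR proteins went both ways (3 lower, 2 higher, camera adjusted p = 0.59), SRPK1 at -0.80 and CLK3 at 0.79. Nonsense-mediated decay (NMD) factors were lower in 16 of 20 genes and higher in 2 (median -0.29, camera adjusted p = 0.00485, and adjusted p = 0.246 with an estimated correlation), with UPF2 at -0.61, EIF4A3 at -0.56 and the release factors ETF1 (-0.58) and GSPT1 (-0.52). Genes with NMD-sensitive transcripts were higher in 8 of 13 and lower in 3 (median 0.28, camera adjusted p = 0.273), led by ATF3 and by CDKN1A (1.43), which also respond to stress.

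Genes reported elsewhere as splicing targets of SRSF1 were compared for total expression. Of 33 such genes 16 fell, 10 rose and 7 did not pass (median -0.07, camera adjusted p = 0.438). SRSF1 itself is on that list, and the largest changes beside it were in CENPE (-2.54), in KIF23 and ECT2, which act in cytokinesis (-1.75 and -1.61), and in VEGFA, a growth factor of blood vessels (1.70, SE 0.0305, 98.6 to 319 CPM). MDM2, the ubiquitin ligase of p53, fell by -1.09. The often-studied targets BIN1 and RPS6KB1 changed by 0.93 and -0.18, BIN1 at only 0.489 ± 0.0818 and 0.936 ± 0.193 CPM. Its adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0102, 0.153 without the second knockdown library and 0.0955 without the second control library. MKNK2, MCL1 and CASP9 did not pass, at log2 changes of 0.04, -0.06 and 0.24.

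Protein synthesis, protein turnover and metabolism divided by group. Cytosolic ribosomal protein genes were higher in 70 of 75 and lower in 2 (median 0.46), by modest changes that reached 0.91 in RPL3 (1592 to 2991 CPM) and 0.86 in RPL34. For this list camera gave an adjusted p of 5.61e-10, and adjusted p = 0.539 with an estimated correlation. These genes have many processed pseudogenes, and reads can be split between the copies. Nucleolar and other MYC target genes went the other way, with 43 of 45 lower and none higher (median -0.69, camera adjusted p = 3.51e-10, and adjusted p = 0.214 with an estimated correlation), among them ODC1, which starts polyamine synthesis (-1.02), and CAD, which starts pyrimidine synthesis (-0.98). Genes of mTOR signalling and translation initiation were mixed, with 12 of 26 lower and 9 higher (median -0.03, camera adjusted p = 0.59), although PDCD4, an inhibitor of the helicase EIF4A, rose by 1.44. Proteasome subunits were lower in 30 of 31 (median -0.44, camera adjusted p = 2.36e-07, and adjusted p = 0.413 with an estimated correlation), PSMC3 by -0.72. Nuclear genes of oxidative phosphorylation were lower in 38 of 39 (median -0.49, camera adjusted p = 1.64e-08, and adjusted p = 0.472 with an estimated correlation), with SDHD at -0.86 and NDUFS1 at -0.83, while none of the 13 mitochondrially encoded genes listed was in the count table. Cholesterol synthesis genes were lower in 18 of 24 and higher in 5 (median -0.28, camera adjusted p = 0.0122, and adjusted p = 0.406 with an estimated correlation), with INSIG1, a brake on sterol synthesis, at -1.32 (1095 to 438 CPM).

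Immediate early, hypoxia-responsive and ATF4 target genes rose as groups, and heat shock genes fell. Of 29 immediate early and AP-1 genes 27 rose and 2 fell (median 1.78), including JUN (3.46, SE 0.0407, 24.3 ± 1.07 to 267 ± 10.1 CPM), EGR1 (3.54) and BTG2 (2.12, 317 to 1379.9 CPM). The camera test gave an adjusted p of 7.64e-08, and adjusted p = 0.198 with an estimated correlation. Hypoxia-responsive and glycolytic genes were higher in 32 of 33 (median 1.41), with P4HA1, a collagen hydroxylase subunit, rising from 85.6 ± 0.634 to 964 ± 4.89 CPM (3.49, SE 0.0333), ALDOC by 2.58, NDRG1 by 2.51 and PFKFB4 by 2.73 (camera adjusted p = 4.37e-11, and adjusted p = 0.246 with an estimated correlation). Targets of ATF4, the transcription factor of the amino acid response, were higher in 21 of 25 and lower in 1 (median 0.79, camera adjusted p = 2.07e-06, and adjusted p = 0.214 with an estimated correlation). Among them DDIT4, an inhibitor of mTOR signalling, rose from 246 to 1022 CPM (2.05), DDIT3, which encodes CHOP, rose by 2.66 (SE 0.0505), and ASNS, asparagine synthetase, from 119 to 352 CPM (1.56). Unfolded protein response genes were higher in 18 of 30 and lower in 9 (median 0.19, camera adjusted p = 0.119), with the sensor ERN1 up by 1.86 and XBP1, the transcription factor it activates, down by -0.75 (1390.4 to 824 CPM). Heat shock genes were lower in 12 of 18 and higher in 3 (median -0.48, camera adjusted p = 0.017, and adjusted p = 0.6 with an estimated correlation), HSPA8 by -1.09 and HSPH1 by -1.14. Targets of p53 went both ways, 16 of 30 higher and 11 lower (median 0.36, camera adjusted p = 0.352), with SESN2 at 2.19, the death receptor TNFRSF10B at 2.49 and the nuclease AEN at -1.88.

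Most interferon-response genes and NF-kB targets were higher and most plasma cell genes lower. Interferon-response genes were higher in 24 of 32 and lower in 3 (median 0.90, camera adjusted p = 0.000154, and adjusted p = 0.214 with an estimated correlation), with XAF1 at 3.33 (3.31 to 33.3 CPM), ISG20 at 2.72 and IRF1 at 1.23. Targets of NF-kB were higher in 14 of 19 and lower in 3 (median 0.33, camera adjusted p = 0.014, and adjusted p = 0.25 with an estimated correlation), with TRAF1 at 3.25 (7.15 to 68.0 CPM) and the chemokines CCL5 at 4.18 and CCL3 at 3.56, the last of which has near-identical copies. Antigen presentation genes of MHC class I and II were split, 9 of 22 higher and 9 lower (median -0.07, camera adjusted p = 0.606), with HLA-DPA1 at -0.74. Of 26 plasma cell genes 17 fell and 7 rose (median -0.41, camera adjusted p = 0.0178, and adjusted p = 0.25 with an estimated correlation). TNFRSF17, the plasma cell receptor BCMA, fell from 351 ± 13.4 to 133 ± 2.42 CPM (-1.40, SE 0.0318) and POU2AF1, a B-lineage coactivator, by -0.99, while DERL3, an endoplasmic reticulum degradation factor, rose by 1.35. Myeloma oncogenes and tumour suppressors were split, 14 of 29 lower and 11 higher (median -0.06, camera adjusted p = 0.59), with CDKN2C at -0.77 (1101 to 643 CPM) and IRF4, on which myeloma cells depend, at -0.64 (1091 to 702 CPM).

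Apoptosis and adhesion genes moved in both directions. Of 25 pro-apoptotic genes 11 fell and 9 rose (median 0.05, camera adjusted p = 0.871), with the BH3-only genes BMF (3.03, SE 0.0375, 32.7 ± 1.36 to 268 ± 5.90 CPM) and BBC3 (1.95) higher and CYCS, cytochrome c, lower (-1.12). Of 17 anti-apoptotic genes 9 rose and 5 fell (median 0.13, camera adjusted p = 0.507), BIRC5, which also acts in mitosis, by -1.98, PIM1 by -0.94 and BCL2 by 0.51. The directional fry test of the anti-apoptotic list pointed down while its median and mean were above 0. Of 20 adhesion and migration genes 12 rose and 6 fell (median 0.22, camera adjusted p = 0.273), with CCR1, a chemokine receptor, at 1.30, CD44 at 0.69, and the integrin ITGB7 at -0.85 (5282 to 2925 CPM).

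**Figure D2:**
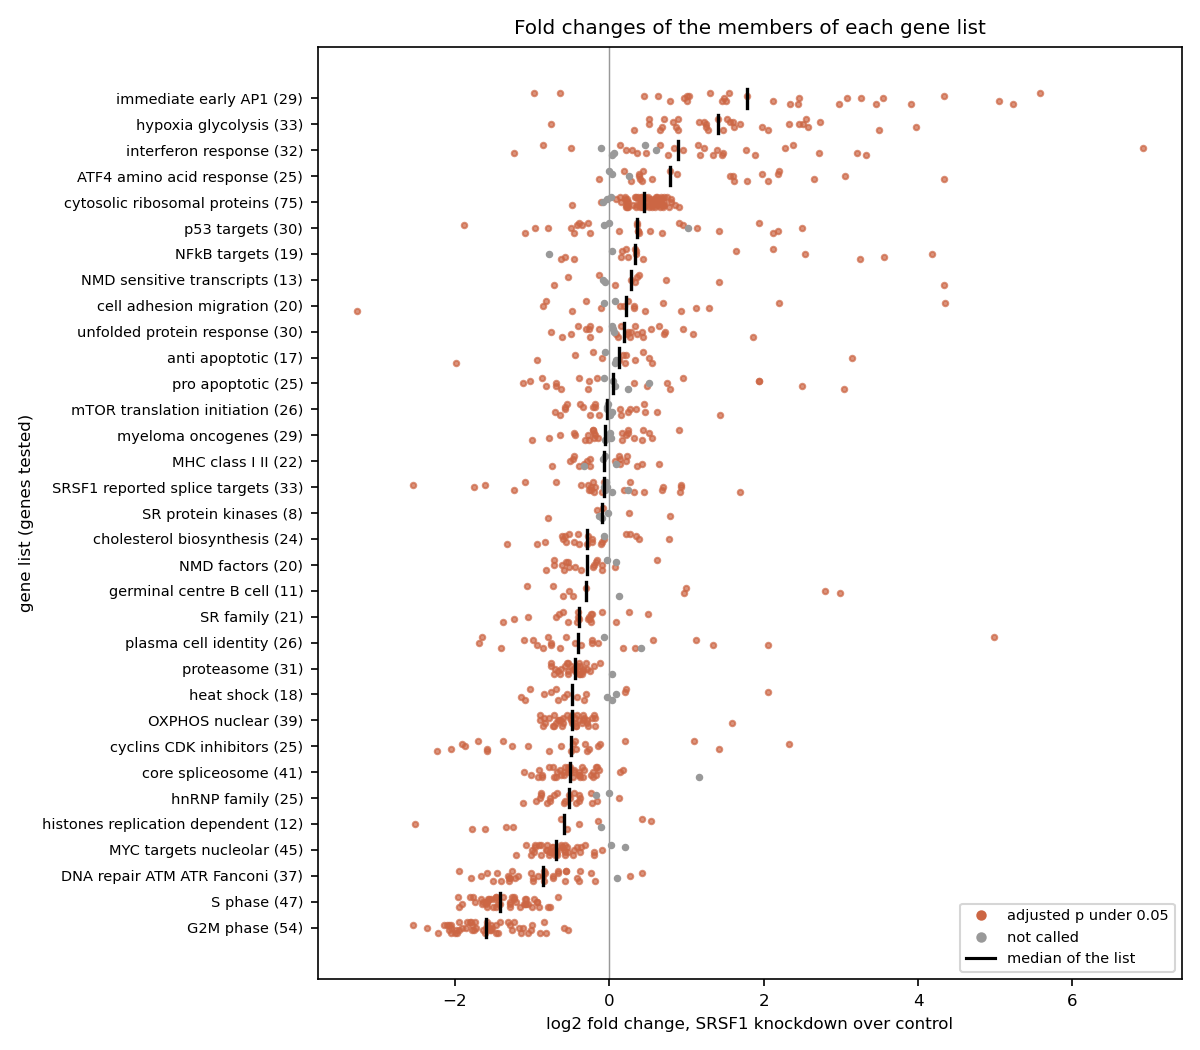
Log2 fold change of knockdown over control for each tested member of the 33 gene lists (1 point per gene, coloured where its adjusted p was under 0.05), with the median of each list as a bar and the number of genes tested in brackets. The lists run from immediate early genes (median 1.78) to G2/M-phase genes (median -1.60).

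Alternative splicing was compared to ask which exons depend on SRSF1, from junction reads that include or skip each event. Of 63960 tested events 315, in 211 genes, changed by at least 10 percentage points of inclusion, 194 with higher and 121 with lower inclusion in knockdown. This share depends on the events counted: 31176 of the 47457 cassette events tested had fewer than 20 reads of the rarer form over the 4 libraries. With at least 20 such reads, 517 of 28009 events changed. Shifts of 10 points were also recovered in only 2% of simulated cassette exons. Higher inclusion took 61.6% of them (95% exact binomial interval 56.0 to 67.0, two-sided exact binomial p = 4.63e-05). Of changed retained introns 37 of 51 were higher (72.5%, exact binomial adjusted p = 0.00885 over 5 event types), and of cassette exons 86 of 141 (61.0%, exact binomial adjusted p = 0.0281). Among all 1183 retained introns tested, changed or not, 710 were higher and 464 lower, so an even split was not their background. The binomial test therefore does not show that changed introns differ in direction from the tested introns as a whole. For introns the direction no longer passed without the second knockdown library (65.5% higher, exact binomial adjusted p = 0.227), without the first control library (71.9%, exact binomial adjusted p = 0.0502) or under the negative binomial dispersion (72.7%, exact binomial adjusted p = 0.938). Nor did it for cassette exons under that dispersion (4 of 5 higher, exact binomial adjusted p = 0.938). The other types did not depart from an even split at adjusted p under 0.05: alternative 3' splice sites had 37 longer and 22 shorter forms, and alternative 5' splice sites 20 and 21. Mutually exclusive exons had 14 events with more and 9 with less of the inclusion form, which holds the upstream exon whatever its length. These events also count in the 61.6%. The 3' splice sites did pass at 50 junction reads (67.9% longer, exact binomial adjusted p = 0.0174) and at 20 reads of the rarer form (64.0%, exact binomial adjusted p = 0.0211). Events of a gene share reads, so they are not independent. With 1 library left out the count of changed events fell to 183 (without the first knockdown library), 218 (without the second), 186 (without the first control library) and 173 (without the second). The count also depended on the test, with 39 events under an estimated negative binomial dispersion and 2323 under the authors' deposited FDR at the same size and coverage. Among events that differed by at least 20 points 54.5% had higher inclusion (exact binomial p = 0.316), 62.5% of the introns and 52.7% of the cassette exons (exact binomial adjusted p = 0.728 for both). Under the authors' deposited FDR 54.2% had higher inclusion.

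The named cassette exons with higher inclusion included exons of ANAPC16 and ANAPC11. Coordinates are those of the deposited tables, and 79.0% of their cassette exons had both ends equal to an annotated GRCh38 exon. An exon of ANAPC16 of 326 bases without coding sequence (chromosome 10, 72220054 to 72220379, exon 2 of 5 in ENST00000621663.4) rose from 27.1% ± 8.77 to 98.5% ± 2.19 inclusion (SD, n = 2), a difference of 71.4 points on 50 to 86 junction reads per library (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.17e-05). A 151-base exon of ANAPC11 (chromosome 17, 81891713 to 81891863) rose from 53.3% ± 11.03 to 100% in both knockdown libraries on 109 to 171 reads (same test and adjustment by edgeR, adjusted p = 6.42e-06). Part of this change lay in the choice of 5' splice site. A 129-base form with the same start was also called, its mean inclusion falling from 0.2025 to 0.0 as a fraction. The 22 bases by which the forms differ rose from 0.6645 to 1.0. In the other direction, a 1934-base region of CIITA, the transactivator of MHC class II genes (chromosome 16, 10923878 to 10925811), fell from 52.9% ± 5.80 to 18.5% ± 1.34 on 339 to 570 reads (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.46e-14). Under the negative binomial dispersion first planned, ANAPC16 (0.157) and CIITA (0.848) lost the call and the 151-base ANAPC11 exon (0.03) kept it (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p). The ANAPC16, 151-base ANAPC11 and CIITA events passed in every fit without 1 library. The other 7 cassette exons chosen by size did not, and the adjusted p that follow are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment after 1 library was left out. RASA4 (42.6 points higher), with knockdown replicates at 80.9% and 13.5%, lost its call without the first knockdown library (adjusted p = 0.975 by edgeR's quasi-likelihood test, Benjamini-Hochberg). AAMDC (52.95 points higher) lost it without the first knockdown (0.0703), first control (0.157) or second control library (0.115), and CENPS-CORT (42.2) without the second knockdown (0.959), first control (0.0941) or second control library (0.845). MSTO1 (-57.2) lost it without the second control library (0.222), and ZNF655 (-55.6) without the second knockdown (0.959) or second control library (0.188). SPNS1 (-43.0) and ZNF263 (-36.3) lost it whichever library was left out, at 0.0809 to 0.659 and 0.112 to 0.602. RASA4 and MSTO1 have near-identical copies in the genome, which can share their reads.

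Among the other event types, the named events included shifts in KAT2A, TIA1, RPL17 and MSTO1. KAT2A, a histone acetyltransferase, used the longer form of an exon more often through an alternative 5' splice site (191 extra bases, chromosome 17, 42119054 to 42119244), rising from 41.6% ± 3.18 to 78.9% ± 4.10 on 457 to 890 reads (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.97e-21). TIA1, itself a splicing regulator, retained an intron more often (chromosome 2, 70227823 to 70229263), rising from 39.5% ± 5.52 to 77.3% ± 6.43 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.47e-05). In RPL17, a ribosomal protein gene, a 190-base non-coding exon (chromosome 18, 49492275 to 49492464) fell by 31.8 points against the exon that replaces it. A 207-base form overlapping it (49492258 to 49492464) was called higher as a cassette exon, from a mean inclusion of 0.299 to 0.4785 as a fraction. In MSTO1 the longer form fell by 63.2 points at a 3' splice site, fell by 59.5 points at a 5' splice site and fell by 62.0 points as a retained intron, 3 overlapping events. The KAT2A, TIA1 and MSTO1 events and the RPL17 event of mutually exclusive exons passed without any single library. The following 8 did not, as measured by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DOT1L, a histone methyltransferase, gained 41.0 points at a 3' splice site and 30.1 points in an overlapping intron, and both calls were lost without the first knockdown (0.449 and 0.245), second knockdown (0.177 and 0.0921) or first control library (0.763 and 0.505). PHYKPL dropped by 41.8 points at a 5' splice site and by 37.4 points in an intron, and both calls were lost without the first knockdown (0.104 and 0.0719) or second control library (0.424 and 0.515), the former also without the second knockdown library (0.0531). AP1G2 (36.6 points higher) lost its call without the second knockdown (0.255) or first control library (0.707), and NUMA1 (33.9) without the first knockdown (0.151) or second control library (0.259). NR2C1 (-53.6 points) and SMPD4 (43.9 higher) lost it whichever library was left out, at 0.0867 to 0.397 and 0.0569 to 0.356.

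Changed events in the fixed gene lists included myeloma and cell death genes. CDKN2C, which encodes the cyclin-dependent kinase inhibitor p18, used an upstream 3' splice site that adds 388 bases outside the coding sequence (chromosome 1, 50969970 to 50970357) more often. Its inclusion level rose from 6.30% ± 0.71 to 32.2% ± 0.21 on 4111 to 6274 reads per library. The adjusted p was the lowest of any named event (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.76e-291). FGFR3, a receptor tyrosine kinase, showed a reciprocal shift of neighbouring coding exons: the 151-base exon (chromosome 4, 1802914 to 1803064) fell from 28.1% ± 0.21 to 13.4% ± 0.35 and the 145-base exon (1803692 to 1803836) rose from 66.9% ± 2.40 to 80.9% ± 1.56. Their adjusted p were 1.83e-18 and 2.03e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and both calls held without any single library. Inclusion of overlapping non-coding regions of HNRNPA3 fell by 15.4 points as a cassette exon and fell by 14.8 points as a 3' splice site. Inclusion of HTRA2 exon 7 of 8, 96 coding bases in a mitochondrial protease, rose from 70.7% ± 0.28 to 86.3% ± 1.06, and a 227-base exon of CFLAR, an inhibitor of caspase 8, fell from 49.5% ± 4.03 to 30.9% ± 0.57. Their adjusted p were 0.00993 and 0.000238 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), but HTRA2 lost its call whichever library was left out (0.122 to 0.444), and CFLAR reached 0.176 without the second control library. Of the 33 events that the naming rule selects, 23 lost the call under the negative binomial dispersion first planned, among them both FGFR3 exons, the HNRNPA3 cassette exon, HTRA2, CFLAR and the MSTO1 3' splice site. Those that kept it in every coverage, dispersion and left-out-library fit included events in CDKN2C, KAT2A, TIA1, RPL17, ANAPC11, HNRNPA3 (3' splice site) and MSTO1 (5' splice site and intron). No event in an SR family gene or in a gene listed as a reported SRSF1 target passed both thresholds.

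**Figure D3:**
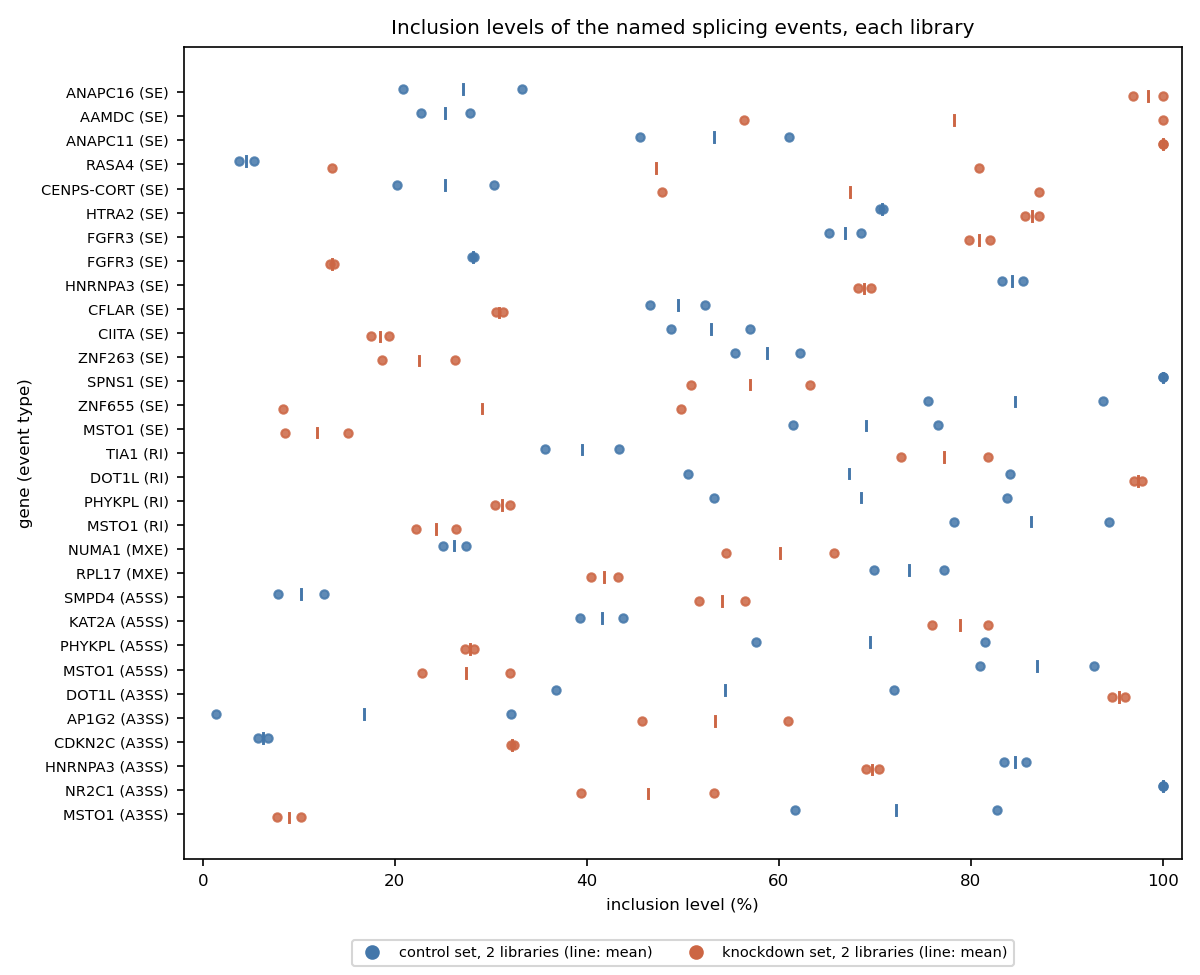
Inclusion level in percent of each splicing event named in the text, with 1 point per library and a line at the mean of the 2 libraries of each set (SE, cassette exon; RI, retained intron; MXE, mutually exclusive exons; A5SS and A3SS, alternative 5' and 3' splice sites). CDKN2C moved from 6.30% to 32.2% with replicates close together, whereas the knockdown libraries of RASA4 lie at 80.9% and 13.5%.

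The sequence of the changed cassette exons was compared because SRSF1 binds GA-rich exonic motifs. Exons with lower inclusion did not carry a detectably different density of the motifs GGAGA and GAAGA: 37 exons had 0.587 ± 0.551 per 100 bases, 68 exons with higher inclusion 0.544 ± 0.968, and 5884 unchanged exons 0.573 ± 0.878 (two-sided permutation test over exons, adjusted p = 0.922 for all 3 comparisons). For the shorter motif GGA the densities were 2.97 ± 1.72 in exons with lower, 2.05 ± 1.81 in exons with higher and 2.38 ± 1.62 in unchanged exons. That is a difference of 0.915 between lower and higher inclusion (permutation test, adjusted p = 0.0402) and of 0.591 between lower inclusion and unchanged (permutation test, adjusted p = 0.0411). Sequence was found for 82.8% of all tested cassette exons but for only 77.8% of the changed ones, so the comparison covers 105 of 135 changed exons. With events chosen by the authors' deposited FDR the density of GGAGA and GAAGA was lower than in unchanged exons in both directions, by differences of -0.087 (permutation test, adjusted p = 0.0403) and -0.17 (permutation test, adjusted p = 3e-05). Direction was read there from a single event kept per exon, which need not be the event that the authors' FDR called. Of the exons with higher inclusion 65.1% overlapped coding sequence, against 76.9% of those with lower inclusion and 82.1% of exons not called with mean inclusion of 10 to 90%, shares that were not tested.

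Genes with a splicing change were then compared with genes changed in expression. Of 210 genes with a changed event tested at both levels, 178 (84.8%) had changed expression, among them CDKN2C (-0.77), FGFR3 (0.43) and KAT2A (0.39), against 83.1% of the other genes. The 178 genes compare with 174.6 by chance, an odds ratio of 1.13 (95% interval 0.768 to 1.71, two-sided Fisher's exact p = 0.576). In 4 equal bins of expression, from lowest to highest, the odds ratios were 0.248 (7 of 16 genes with a changed event), 0.799, 1.518 and 1.057 (Fisher's exact p = 0.00605, 0.621, 0.452 and 1, not adjusted). With the 4 bins combined the odds ratio was 0.887 (exact Mantel-Haenszel p = 0.539). Under the authors' deposited FDR of the splicing events, 1528 genes had a changed event and the odds ratio was 0.798 (Fisher's exact p = 0.002).

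Transcript levels were compared as a further view of isoform use. Of 24934 transcripts tested by limma, 4395 in 3463 genes changed at a Benjamini-Hochberg adjusted p under 0.05, 1946 higher and 2449 lower, and at least 2-fold 941 higher and 851 lower. With the libraries scaled to equal totals 1740 were higher and 3058 lower, and the 2-fold split turned to 841 higher and 1023 lower. It also turned with the replicate number as a block, to 600 higher and 636 lower. In 88 of 6141 genes with at least 2 tested transcripts, one transcript rose while another fell. LUC7L, which encodes a U1 snRNP-associated protein, had XM_017023438.2 higher by 2.06 on the log2 scale and NM_201412.2 at -1.85. SFPQ, which encodes a paraspeckle and splicing protein, had XM_017002054.2 at 1.08 and NM_005066.2 at -1.22, and CDKN2C NM_078626.2 at 0.96 and NM_001262.2 at -1.16. These 3 genes were chosen after the values were seen. The unit of the transcript values is not named, and assignment of reads between isoforms adds uncertainty that the test does not see. Limma called 0 transcripts when either control library was left out, with 5705 (without the first) and 5772 (without the second) at an unadjusted p under 0.05, and called 3265 without the first and 2877 without the second knockdown library.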

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

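The dispersion of the splicing test, the rarer-form minimum and the authors' transcript calls were chosen only after the data were seen. The negative binomial dispersion was first written, and all other alternatives were set beforehand. Of 166 genes other than SRSF1 that the naming rule selects and that were past the threshold, 159 kept sign and call in every alternative. BIN1, HBB, SRSF5 and SRSF6 lost the call in fits without 1 library. SRSF1, counted apart, kept sign and call at -1.16 to -1.25. The count of changed genes lay between 7930 and 10341. Scaling by library size alone moved the share of higher genes to 55.6%. Limma on log2(FPKM + 1) and log2(FPKM + 0.1) gave 40.5% over the 9897 genes past the FPKM filter. The medians of all genes were then -0.0896 and -0.1057. Without that filter log2(FPKM + 1) gave 48.4% and a median of 0.0041. At least 2-fold changes fell to 688 on log2(FPKM + 1), 687 without its filter and 1078 on log2(FPKM + 0.1), run with the filter only. In these fits the added constant itself limits low genes. MCL1 was at 0.01 with library size only and MKNK2 at -0.02 on all 3 FPKM fits. DESeq2 called 8965 genes.

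Of the lists, camera called 20, and 0 with an estimated correlation (fry 32). The lists that lost the call included some whose estimate did not exceed the preset. Fry put the anti-apoptotic list lower (adjusted p = 0.0136). The direction of the pro-apoptotic list turned in camera with no filter (adjusted p = 0.927) and without 1 library (adjusted p of 0.857 to 0.926). Beyond what the constant fixes, the cause was not tested for any of these results.

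Splicing depended on the processing. Instead of 315 events there were 517 at 20 reads of the rarer form, 39 with the negative binomial dispersion, 143 at a difference of 0.2, 204 at an adjusted p under 0.01, 2323 under the authors' deposited FDR and 173 to 218 without 1 library. Higher inclusion took 61.5% with the negative binomial dispersion (exact binomial p = 0.2), 54.5% at a difference of 0.2 and 54.2% under the authors' deposited FDR. For 5' splice sites it took 53.3% at 50 reads, 51.7% at 20 reads of the rarer form, 54.2% at an adjusted p under 0.01 and 45.5% to 57.7% without 1 library. For mutually exclusive exons it took 50% with the negative binomial dispersion, 46.5% at a difference of 0.05, 37.5% at 0.2 and 50% to 54.2% without 1 library. Of the 33 events the naming rule selects, 17 lost the call in a fit without 1 library and 24 in another alternative (23 under the negative binomial dispersion), and 9 kept it in every coverage, dispersion and left-out-library fit. The overlap odds ratio was 0.927 for 2-fold genes, 0.798 under the authors' deposited FDR and 0.857 to 1.809 without 1 library. The motif difference between lower and higher inclusion was 0.915 for GGA. For GGAGA and GAAGA it was 0.043, and 0.084 under the authors' deposited FDR. Against unchanged exons the difference was 0.591 for GGA in exons of lower inclusion. For GGAGA and GAAGA under that FDR it was -0.087 and -0.17 for lower and higher, with direction read from a single event kept per exon. Changed transcripts numbered 3701 by the authors' deposited calls (1551 higher, 2150 lower), 764 with no filter and 0 to 3265 without 1 library, where the lone library is assumed to vary like the others. The cause was not tested.

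The titles share the numbers 1 and 2, but same-numbered libraries did not deviate together (correlation -0.017 over 12457 genes). With the number as a replicate block 9981 genes changed, 2319 at least 2-fold, 2389 transcripts changed, and the overlap odds ratio was 1.095, or 1.051 with the block in the expression fit only. For splicing the position in the cell served as the number, matched from the data, and with the block 294 events changed, 61.6% of them higher.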

Other observations

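The ratio of library depths and the level of 3 B cell transcripts were chosen as tests after their results were seen. The dispersion of the splicing test and the minimum of 20 reads of the rarer form were chosen after the data were seen.

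Germinal-centre B cell genes moved in both directions. Of 11 tested, 6 fell and 4 rose, and the list did not pass (camera adjusted p = 0.608), with a median log2 change of -0.31, a mean of 0.38 and a camera direction of lower. CIITA and BACH2, which restrains plasma cell differentiation, fell by -0.47 and -0.31. MME, the surface marker CD10, rose by 2.98 (SE 0.298, 0.275 to 2.18 CPM) and BCL6, the master regulator of germinal-centre B cells, by 2.79 (SE 0.355, from 0.226 CPM), both at low levels. Few markers of other cell types were tested. Both myeloid markers rose, CD68 from 0.915 to 5.08 CPM and ITGAM to 0.57 CPM. Of 2 T and NK cell markers CD2 was called higher, from no control read to 0.291 CPM. Of 3 stromal and epithelial markers ACTA2 rose by 1.08, and KRT5 (-3.19) and PECAM1 fell. Of the erythroid markers EPOR fell by -0.60, and HBB, at 0.274 and 0.108 CPM, was called lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0429) but not once control library 1 (0.186), control library 2 (0.102), knockdown library 1 (0.339) or knockdown library 2 (0.0523) was left out. None of the 9 nuclear long non-coding RNAs listed was in the count table.

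The authors' deposited KEGG table had 6 of 311 terms at an adjusted p under 0.05. By enrichment ratio in the authors' deposited table these were cell cycle (3.08, 46 of 124 genes), DNA replication (4.14, 18 of 36), p53 signaling (2.19), base excision repair (2.76), the Fanconi anemia pathway (2.30) and pyrimidine metabolism (1.89). In HMGB1, a chromatin protein, the transcripts moved apart most, by -3.98 and 1.52, and this gene was chosen after its values were seen.

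Genes at least 2-fold higher outnumbered those at least 2-fold lower, 1743 to 583. Deeper knockdown libraries are excluded as the cause, since their mean count total was 0.965 of the control mean, a ratio known before its prediction was written. Uniform background reads are excluded too, because the median gain per kilobase of the risers was 192 times the mean gain of genes with no control read. The excess may lie in genes of low expression alone: at a mean of at least 10 CPM 47.0% of the 2-fold calls were higher, against 66.6% at 1 CPM or more and 34.0% at 100 CPM or more. An effect of SRSF1 loss on silent genes was not tested against other causes.

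Cell cycle lists fell while immediate early, ATF4 target, glycolysis and ribosomal protein lists rose. GC content or gene length bias is excluded as the whole cause, since the S-phase median was -1.33 after a smooth trend on both was removed, 94.5% of its size. Cells of a T, NK, myeloid, erythroid, stromal or epithelial type are excluded, because at most 11.8% of the markers of any such type reached 1 CPM in the knockdown libraries. Markers of germinal-centre B cells did reach the share set beforehand (9 of 16, 56.2%, against 6 in control), but such cells are excluded because MS4A1, CD22 and PAX5, a set not reported in full, reached at most 0.0255 CPM there, with the limit set after the levels were seen. A difference in culture state or handling between the groups could produce the same pattern as SRSF1 knockdown, is confounded with it here and was not tested.

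The authors' deposited FDR called 2323 splicing events and the edgeR test used here 315. Of the 2009 events that only the authors' deposited FDR called, 60% had an unadjusted p under 0.05 (edgeR quasi-likelihood test), between the 80% and 50% set beforehand, so a stricter threshold on the same evidence stays undecided. Few reads of the rarer form also stays undecided, since with at least 20 such reads the authors' calls were 3.43 times as many, between the limits of 2 and 4 set beforehand. No biological explanation applies to a difference between 2 tests of the same reads.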
